A study of Escherichia coli K-12 with 43 samples.

How the data were processed

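Escherichia coli K-12 MG1655 was grown in LB at 37 °C to an OD600 of 0.2, when cefsulodin (10 µg/ml), mecillinam (0.03 µg/ml) or both were added, per the labels' protocols. Untreated cultures were sampled at the same times. RNA (20 µg) was hybridised to the Affymetrix E. coli Antisense array, a one-colour oligonucleotide array in which each transcript is read by a probe set. The 43 arrays form 16 groups, 4 treatments at -5, 5, 20 and 40 min relative to the addition of the drugs. Per the labels, the replicates were biological, at least 3 were collected for each condition, and only some of them were hybridised.

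The deposited values are log2 expression values per probe set made with RMA, per the submitters' processing notes. RMA corrects the background, normalizes the arrays to one distribution of intensities and summarises the probes of a set. Its version, and whether all 43 arrays were processed together, are not given in the sources used here. A normalization to one distribution hides any change in the total amount of mRNA per cell, so every difference is relative to the other transcripts. The array medians over all probe sets lay between 7.54 and 7.74. Arrays give no count of molecules, and it is their number per group that limits the precision.

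The table held 7312 probe sets, of which 22 were array controls. The platform annotation listed 4398 of them and did not list 2914, among these 2733 intergenic probe sets, which are unnamed here. Of the listed probe sets, 3804 had 1 gene symbol, 594 had several and 0 had none. The annotation joins the symbols of several strains, so symbols were updated through the gene identifier of MG1655. 4286 probe sets had exactly 1 such identifier, and 1 of them was left out because the locus tag in its name differed. The 42 probe sets with more than 1 identifier and the 70 with none named no gene. Where a gene had more than 1 probe set (78 genes), the brightest over all arrays stood for it, which left 4185 genes. For 58 of them it was an intergenic probe set. Gene names were taken from these tables alone, and genes are given by symbol and locus tag without coordinates because no genome build is named for the probe sets.

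One linear model with a mean for each of the 16 groups was fitted to the 43 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), which gave 27 residual and 3.40 prior degrees of freedom. The pooled spread was used because several groups held 2 arrays. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 4185 genes, and a gene was said to have changed, risen or fallen at an adjusted p below 0.05. Differences are on the log2 scale with the standard error of the model. There were 19 comparisons. Each treatment was set against untreated cultures at each time, the combination against each drug alone at 40 min, and mecillinam against cefsulodin at 5, 20 and 40 min. Untreated cultures at 40 min were set against those at -5 min, and the combination effect at 40 min against the sum of the single-drug effects (called non-additive where it differed). P-values set each difference against the spread of replicate cultures pooled over all 16 groups, not against that of the groups compared alone.

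The groups, comparisons, tests, 23 gene lists and most alternatives were fixed before the data were examined. The lists held the Rcs phosphorelay components, other genes of the Rcs regulon, colanic acid synthesis, the Cpx, sigma E and Bae regulons, phage shock, the SOS response, heat shock, the general stress (sigma S) regulon, acid resistance, osmotic stress, oxidative stress, flagella and chemotaxis, curli, peptidoglycan synthesis, peptidoglycan hydrolysis and recycling, cell division and shape, outer membrane proteins, lipopolysaccharide modification, ribosomal proteins, the TCA and glyoxylate cycles, and reference genes. Some genes stand in more than 1 list, such as rcsA, spy, degP and osmB. Some list members, such as rprA, micA, rybB, tisB, ecnB and mpl, had no tested probe set. Lists were tested with limma's camera at its preset correlation between genes of 0.01, adjusted over the 23 lists, with a correlation estimated for each list and with fry, whose directional test asks whether the genes of a list move on balance one way. Members that passed are counted after adjustment over all genes and, where stated, adjusted over the list alone.

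The genes named were set by a rule. For the combination against untreated cultures at 40 and 20 min, these were up to 10 risers and 10 fallers with the largest difference among genes past the threshold whose arrays did not overlap between the groups. For the other comparisons they were the first 5 each way. Up to 4 members of each list with the largest difference could be named, and rcsA, wza, cpxP, degP, rpoE, spy, sulA, ibpB, osmB, flhD, mrcA, mrcB and mrdA were named whatever their value. Genes named outside the rule are said to be so.

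Arrays of a group correlated at 0.939 to 0.994, and the arrays of a pair held exactly equal values, with no tolerance, for at most 4 genes. The replicate numbers of the labels were checked as a pairing of the treated with the untreated cultures through the correlation of their deviations from the group means. Every pair correlated above 0.1 for the combination at 40 min (0.301 to 0.669, 4 pairs), the combination at 20 min (0.417 to 0.823, 3 pairs) and mecillinam at 40 min (0.259 to 0.537, 3 pairs). So did those of cefsulodin and mecillinam at 20 min and mecillinam at 5 min, where 2 arrays per drug are too few to tell a pairing. The same check between the treated groups at 40 min, added after the data were seen, gave 0.283 to 0.527 for the combination with cefsulodin, 0.304 to 0.535 for the combination with mecillinam and 0.375 to 0.725 for mecillinam with cefsulodin (3 pairs each). Fits with the replicate number as a block are therefore given beside those results where they change a call or move a count by over 1.5 times. The block fixed at first used 1 effect per number over all times, and a block of numbers within each time was added after the arrays at 20 min were seen to separate by number.

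The other alternatives fixed at that stage were a shift of each array to one median, quantile normalization again, the mean of a gene's probe sets, all probe sets in place of genes, leaving out the dimmest 25% of genes, fitting only the groups compared, an intensity trend with a robust prior, array weights, the culture as a random block, the difference from the -5 min group, a 2-fold minimum and leaving out each array in turn. Added after the data were seen were the genes with a single listed symbol, the arrays of the time points compared alone, and fits without the arrays numbered 4 at 40 min or 2 at 20 min.

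The test was tried on simulated data, 5 simulations in which 200 of the 4185 genes were changed. With 1 spread per gene, the combination comparison at 40 min recovered 63.0% of genes changed by 0.5 on the log2 scale, 94.6% of those changed by 1 and 99.7% of those changed by 2, with 4.99% false calls. With a spread per gene and time drawn from the arrays, false calls came to 13.7% for the combination at 40 min and 43.7% at 20 min, because the arrays varied more at 20 min (median residual SD 0.204) than at -5, 5 or 40 min (0.142, 0.126 and 0.174). A list of 18 genes raised by 0.5 on the log2 scale was called in 20 of 20 simulations of the comparison at 40 min, and 0 lists were called with no change. In the arrays the estimated correlation ran from 0.027 (reference genes) to 0.768 (ribosomal proteins). At -5 min, before any drug, camera called 2 lists for cefsulodin, 1 for mecillinam and 0 for the combination. The simulation therefore does not give the rate of false list calls in these arrays. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.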

Results

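Expression was measured in E. coli K-12 MG1655, a laboratory strain, around the addition of cefsulodin, mecillinam or both. Both drugs are beta-lactams. Cefsulodin, a cephalosporin, binds the penicillin-binding proteins encoded by mrcA and mrcB, and mecillinam, an amidinopenicillin, binds the one encoded by mrdA. The series addresses how expression changes when low concentrations of these drugs disturb peptidoglycan. Untreated cultures gave 3, 2, 3 and 4 arrays at -5, 5, 20 and 40 min. Cefsulodin and mecillinam each gave 2, 2, 2 and 3, and the combination gave 3, 3, 3 and 4. The labels of the arrays numbered 4 at 40 min, 1 untreated and 1 with the combination, add a suffix of unstated meaning to that number, and they were read as biological replicates. The groups at -5 min precede the drugs. The number of arrays sets the precision, with a median standard error per gene of 0.129 log2 units for the combination against untreated cultures at 40 min and 0.182 for a single drug at 5 min.

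**Figure D1:**
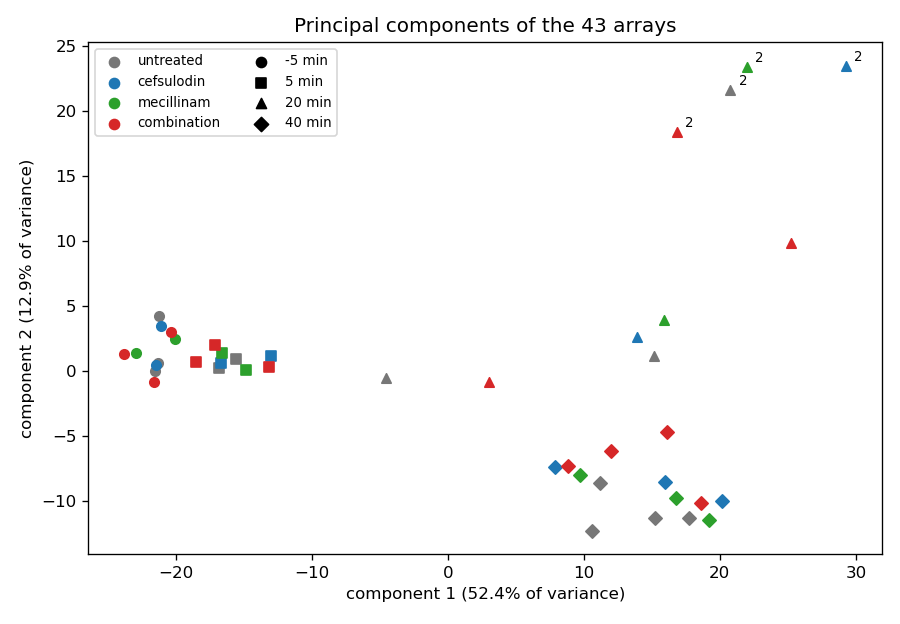
Each point is one of the 43 arrays on the first and second principal components of the genes tested, which carried 52.4% and 12.9% of the variance, with colour for the treatment and shape for the time. Along the first component the arrays at -5 and 5 min (-23.77 to -12.98) lie apart from the later ones (-4.52 to 29.27), while those at 20 and 40 min overlap. The 20 min arrays numbered 2, marked in the plot, lie apart from the others along the second.

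The combination at 40 min was set against untreated cultures to ask which transcripts respond when both drugs are present. The largest rise of a gene was that of osmB (b1283), a lipoprotein gene known to respond to osmotic shock. Its log2 level was 11.96 ± 0.44 (SD, n = 4) with the combination and 7.73 ± 0.29 (SD, n = 4) in untreated cultures, an 18.8-fold difference. The level was 8.06 ± 0.09 (SD, n = 3) with cefsulodin and 8.44 ± 0.62 (SD, n = 3) with mecillinam. rcsA (b1951), the auxiliary regulator of the Rcs phosphorelay, rose from 4.76 ± 0.18 to 8.22 ± 0.24 (SD, n = 4 each). Its lower level lay below the 25th percentile of all probe sets (6.20 to 6.31 over the arrays), as did the untreated levels of bdm, wcaD and wcaE. Their distance from background was not measured, so their differences hold only for the values as deposited. spy (b1743), a periplasmic chaperone, rose 9.30-fold, and ivy (b0220), a periplasmic lysozyme inhibitor, 7.14-fold. flhD (b1892), which with flhC encodes the master regulator of flagellar genes, fell 2.56-fold, from 8.69 ± 0.10 to 7.33 ± 0.25 (SD, n = 4 each).

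In all, 69 of 4185 genes changed (limma), 66 up and 3 down, and 32 of them by at least 2-fold. After osmB, the log2 rises were 3.67 ± 0.25 (SE) for ymgD (b1171), 3.46 ± 0.16 for rcsA (adjusted p = 1.9e-16), 3.22 ± 0.19 for spy and 2.84 ± 0.22 for ivy. They were 2.67 for ymgG (b1172), 2.50 for ypeC (b2390), 2.48 for bdm (b1481), 2.45 for hslJ (b1379) and 2.40 for ycfJ (b1110). Besides flhD, flhC (b1891) fell by 0.54 and cas3 (b2761), a CRISPR nuclease gene, fell by 0.40 on the log2 scale. The cas3 call ended when only the groups compared were fitted (adjusted p = 0.235), without the arrays numbered 4, a fit added after the data were seen (0.194), and relative to the -5 min groups (0.926), as did the flhC call in the last (0.513). The 66 risers had a median of 0.99 at 40 min, and the same genes had medians of 0.15 at 20 min, 0.00474 at 5 min and 0.03 at -5 min. Their median was -0.03 with cefsulodin and 0.06 with mecillinam at 40 min. Of the 69 genes, 34 belonged to a fixed list and 35 to none. With the replicate number as a block, 110 genes changed (78 up, 32 down), and with the number as a block within each time 205 did (148 up, 57 down). All 69 were among both. Array weights gave 135 (114 up, 21 down). Leaving out each array in turn gave 60 to 87 genes. Without both arrays numbered 4, which had array weights of 0.277 (untreated) and 0.233 (combination), 63 genes changed (58 up, 5 down), 57 of them among the 69. Relative to each treatment's own -5 min group, 36 genes changed, each of them among the 69.

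**Figure D2:**
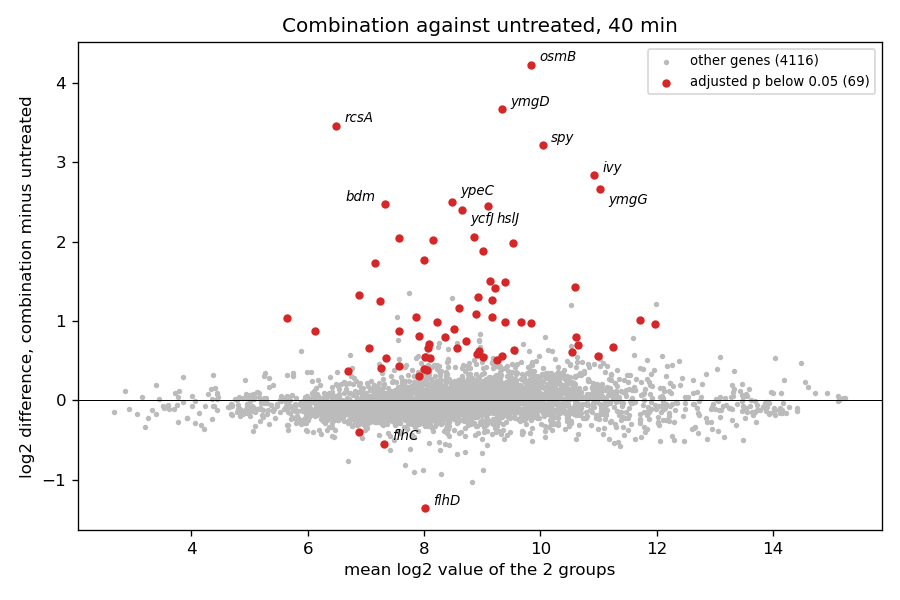
The log2 difference between the combination and untreated cultures at 40 min (vertical axis) is plotted against the mean log2 value of both groups (horizontal axis), one point per gene. The 69 genes past the test are in red, of which 66 lie above 0 and 3 below.

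The Rcs phosphorelay answers to damage of the outer membrane and peptidoglycan, and its regulon held the largest rises. Of 18 other measured genes of the Rcs regulon, 12 rose over all genes and 13 adjusted over the list alone, with a list median of 1.90 (camera, adjusted p = 2.5e-64). Among the 6 phosphorelay components, rcsA and rcsB (0.61) rose over all genes, and 3 rose adjusted over the list alone (median 0.32, adjusted p = 2.0e-09). Of 23 genes for colanic acid, the capsular polysaccharide under Rcs control, 8 rose and 9 did adjusted over the list alone. Their median was 0.17 (adjusted p = 1.1e-11). wcaD rose by 1.04, wzc by 0.87, wcaE by 0.87 and wza, which encodes the export channel, by 0.44. The wza call ended without untreated array 2 (adjusted p = 0.0863), combination array 1 (0.0991) or combination array 4 (0.0803), without both arrays numbered 4 (0.164), relative to the -5 min groups (0.984) and when only the groups compared were fitted (0.139). With an estimated correlation the 3 lists kept their calls, at adjusted p = 2.7e-08, 0.0006 and 0.0438 in the order given. In the fit with a block within each time the colanic acid list had adjusted p = 0.0773 with an estimated correlation.

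The Cpx system senses misfolded envelope proteins. Of its 18 genes, 4 rose over all genes and 11 adjusted over the list alone, with a median of 0.40 (camera, adjusted p = 1.5e-15, and adjusted p = 0.0146 with an estimated correlation). The 4 were spy, yebE (1.26), the membrane protease gene htpX (0.99) and the periplasmic protease gene degP (0.99 ± 0.16, SE). cpxP, which encodes the inhibitor of the Cpx sensor, differed by 1.20 ± 0.33 (SE, adjusted p = 0.051) and did not pass. Of the 18, 10 rose with the block within each time. cpxP passed with the replicate block (adjusted p = 0.0152), with the block within each time (0.0031), with the mean of its probe sets (0.0104), with array weights (0.0003), with the arrays of the time points compared (0.0265), and without untreated array 1 (0.0474), untreated array 2 (0.0454) or combination array 4 (0.0106). Of 24 genes of the general stress regulon, 5 rose and 10 did adjusted over the list alone (median 0.27, adjusted p = 7.6e-14, and adjusted p = 0.0241 with an estimated correlation). These included osmY (1.99), yjbJ (1.51), osmE (1.06) and osmC (0.98), and with the block within each time 8 rose.

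Both degP and fkpA (0.80), a periplasmic folding factor gene, rose among 26 measured genes of the sigma E regulon, with the same 2 adjusted over the list alone. The list median was 0.13 (adjusted p = 0.00057, and adjusted p = 0.0976 with an estimated correlation), and after quantile normalization again the list did not pass (adjusted p = 0.0615). rpoE itself differed by 0.50 (adjusted p = 0.351) and passed with array weights (0.0361). Among 20 osmotic stress genes, osmB, osmY, osmE and osmC rose, and 6 did adjusted over the list alone. The median of that list was -0.05 while its mean was 0.41, and camera called it higher (adjusted p = 6.5e-05, and adjusted p = 0.0976 with an estimated correlation). With the block within each time the last value was 0.0472.

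All 17 heat shock genes, which encode cytoplasmic chaperones and proteases, were higher with the combination, with a median of 0.47 (camera, adjusted p = 1.8e-07, and adjusted p = 0.187 with an estimated correlation), while fry did not call them (adjusted p = 0.0771). Of these genes 0 passed over all genes or adjusted over the list alone (limma). The largest differences were 1.29 ± 0.47 (SE) for ibpA and 1.05 ± 0.47 for ibpB, small heat shock proteins, 0.84 for htpG and 0.80 for hslU. Of the 17, 0 rose over all genes with the replicate block and 6 adjusted over the list alone, fry called the list (adjusted p = 0.0411), and adjusted p = 0.162 with an estimated correlation. With the block within each time, chosen after the data were seen, 11 of the 17 rose, and adjusted p = 0.0149 with an estimated correlation. ibpA, ibpB, htpG and hslU were then among the risers (adjusted p = 0.0029, 0.0033, 0.0002 and 0.0013). ibpB also passed when only the groups compared were fitted (0.0212) or the arrays of the time points compared (0.0019). All 46 flagellar and chemotaxis genes were lower, with a median of -0.36 (camera, adjusted p = 4.4e-18, and adjusted p = 0.058 with an estimated correlation). Over all genes flhD and flhC fell, and 25 fell adjusted over the list alone. Differences were -1.02 for flgC, -0.93 for flgE and -0.90 for fliA, the flagellar sigma factor gene, none of which passed over all genes. Of the 46, 13 fell with the replicate block, flgE among them (adjusted p = 0.041), and adjusted p = 0.0395 with an estimated correlation. With the block within each time 20 fell, among them flgC, flgE and fliA (0.0086, 0.0191 and 0.0205), and the list had adjusted p = 0.035 with an estimated correlation.

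Smaller shifts were called by camera for 3 lists, of which fry called the first (adjusted p = 0.0164). The 18 oxidative stress genes had a median of 0.17 (adjusted p = 0.00013, and adjusted p = 0.058 with an estimated correlation), with 0 members past over all genes and 3 adjusted over the list alone. With the replicate block 1 member rose, ahpF (0.46), and adjusted p = 0.0404 with an estimated correlation, and with the block within each time 3 did, ahpF, ahpC (0.45) and dps (0.71), all named after their values were seen. Adjusted p for the list was then 0.0293 with an estimated correlation. The 7 phage shock genes had a median of 0.17 (adjusted p = 0.0267, and adjusted p = 0.172 with an estimated correlation), and the call ended without untreated array 1 (adjusted p = 0.0733) or combination array 4 (0.0538). The 7 curli genes had a median of -0.19 (adjusted p = 0.0126, and adjusted p = 0.238 with an estimated correlation), a call that ended without combination array 2 (adjusted p = 0.0697). In both lists 0 genes passed over all genes or adjusted over the list alone (limma). Over the 23 lists, camera called 12 with its preset correlation and 5 with an estimated one, and fry called 10.

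The genes of the drugs' targets stood close to their untreated levels. mrcA differed by -0.03, mrcB by 0.07 and mrdA by 0.06, none past the test. Of 35 peptidoglycan synthesis genes 0 passed over all genes (limma), and 1 adjusted over the list alone, dacC at 0.73 (list adjusted p = 0.0903). The 37 genes of peptidoglycan hydrolysis and recycling and the 26 of cell division and shape had medians of 0.05 and 0.06 with 0 past either way (adjusted p = 0.0658 and 0.0569). With a block some wall genes rose over all genes. dacC did with the replicate block (adjusted p = 0.0181) and with the block within each time (4.8e-05), and with the latter ldtC (0.57, adjusted p = 0.00053), slt (0.44, adjusted p = 0.0116) and ldtB (0.49, adjusted p = 0.048) of the hydrolysis list did as well, the last 3 named after their values were seen. The division and shape list passed with the replicate block (adjusted p = 0.0485, and adjusted p = 0.321 with an estimated correlation) and without untreated array 4 (0.0457), combination array 1 (0.0294) or combination array 4 (0.034). The hydrolysis list passed without untreated array 2 (0.0285) or combination array 4 (0.0252), and the synthesis list without untreated array 4 (0.043) or combination array 3 (0.0488). In the SOS regulon, which answers to DNA damage, 0 of 25 genes passed either way (median -0.10, adjusted p = 0.393), and the division inhibitor gene sulA differed by -0.18 (adjusted p = 0.799).

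Among 18 outer membrane protein genes ompX rose by 0.96, alone in the list under both adjustments (median 0.09, adjusted p = 0.0827), and with the block within each time 3 genes rose. The list passed without untreated array 1 (adjusted p = 0.0286) or combination array 4 (0.0039). In the Bae regulon of 8 genes spy alone rose under both adjustments. The median was -0.05 and the mean 0.38 (adjusted p = 0.121), while fry called it (0.00335), as did camera without untreated array 3 (0.0476). With 0 members past either way, the medians were 0.09 for 10 acid resistance genes (adjusted p = 0.352), -0.07 for 54 ribosomal protein genes (0.875), -0.03 for 20 TCA and glyoxylate genes (0.640), -0.04 for 16 lipopolysaccharide modification genes (0.02 after quantile normalization again, 0.993) and 0.05 for 12 reference genes (0.183). Camera gave the ribosomal, TCA and lipopolysaccharide lists the direction up, against the sign of their medians. Without combination array 4 the ribosomal list passed (adjusted p = 0.0269).

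**Figure D3:**
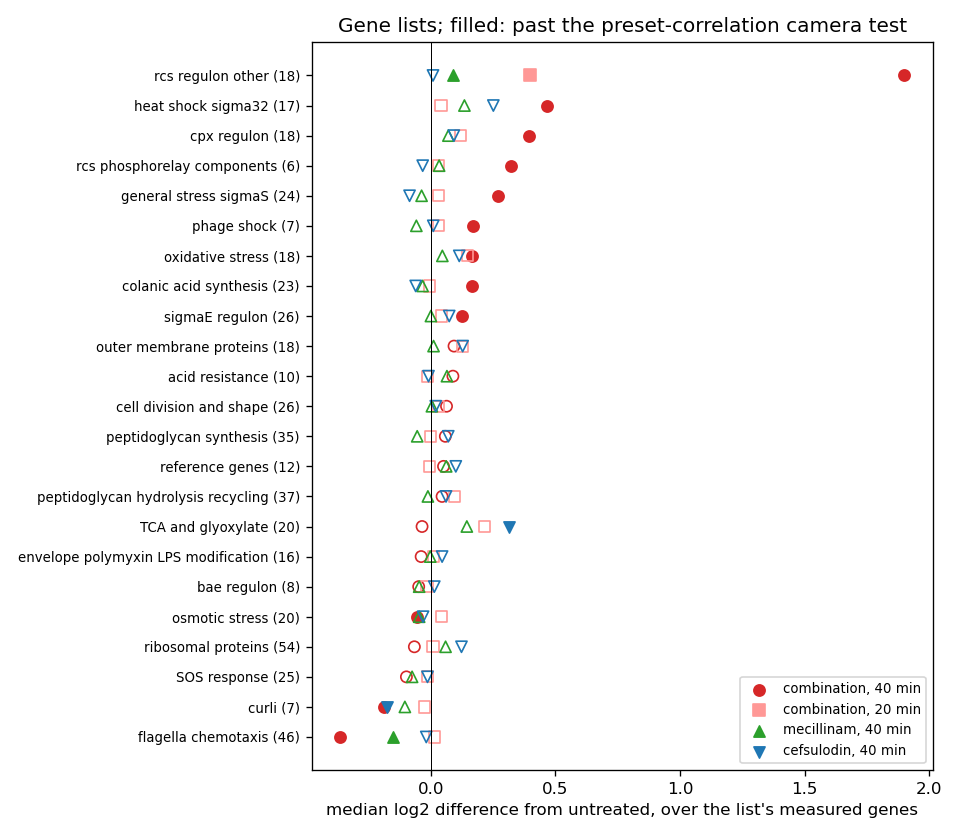
The median log2 difference from untreated cultures (horizontal axis) is shown for each of the 23 gene lists, with the number of measured genes in parentheses, for the combination at 40 and 20 min and for each drug alone at 40 min. Filled symbols passed camera with its preset correlation. The other Rcs genes reach 1.90 with the combination at 40 min and 0.40 at 20 min.

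At 20 min the same comparison asked how early the response was visible. osmB was already 2.98-fold higher, at 9.61 ± 0.50 with the combination and 8.04 ± 0.17 in untreated cultures (SD, n = 3 each). It was 1 of 5 genes that rose, with 0 falling and 143 at an unadjusted p below 0.05 (limma). The others were ypeC (1.14), yaiY (b0379, 0.86 ± 0.14, SE), ycfJ (0.78) and mliC (b1639, 0.72), which encodes a membrane lysozyme inhibitor. All 5 were among the 66 risers at 40 min, against 0.079 in independent lists, and the untreated arrays of both comparisons were different ones. Arrays of the same treatment and number may come from 1 culture (consensus correlation 0.199), so the comparisons need not be independent. Of the 66 genes, 37 were higher at -5 min, before the drugs, 37 at 5 min and 55 at 20 min. Of the 18 other Rcs genes 16 were higher, 4 rose over all genes and 12 did adjusted over the list alone. The list median was 0.40 (camera, adjusted p = 3.8e-21, and adjusted p = 0.00055 with an estimated correlation).

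Also at 20 min, ymgD differed by 1.31 (adjusted p = 0.063) and ivy by 0.91. rcsA differed by 0.48, spy by 0.39, cpxP by 0.51, degP by 0.22, wza by 0.12, rpoE by 0.09, sulA by 0.14, mrcB by 0.08, mrcA by -0.10, mrdA by -0.33, ibpB by -0.38 and flhD by -0.41, none past the test. With the block within each time 9 genes rose, adding ymgD (adjusted p = 0.0397), ivy, nagB and yijO, the last 2 named after their values were seen, and the TCA and glyoxylate list passed (0.00835, and adjusted p = 0.856 with an estimated correlation). The arrays at 20 min varied more than the pooled spread of the model, and when only they were fitted 0 genes passed (limma, osmB at adjusted p = 0.364). Relative to the -5 min groups 1 gene, mliC, rose. Without combination array 1, 3 genes rose and ypeC did not pass (adjusted p = 0.0811). ycfJ did not pass without that array (0.669), combination array 3 (0.0828), untreated array 1 (0.138) or untreated array 2 (0.298). Nor did ycfJ pass after either renormalization (0.0512 and 0.0672) or with array weights (0.451). Lists called rose from 1 to 9 without untreated array 2, the added ones led by ribosomal proteins (adjusted p = 1.5e-09). They rose to 4 without combination array 3, to 3 without combination array 2, and to 2 without untreated array 1, untreated array 3 or combination array 1.

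At 5 min and at -5 min the combination cultures gave 0 changed genes (limma), with 25 and 64 at an unadjusted p below 0.05 and 0 lists called. osmB differed by 0.02 at 5 min and 0.03 before the drugs, rcsA by -0.03 and 0.06, and spy by -0.00142 and 0.06. Without untreated array 1 at 5 min, 2 genes passed.

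**Figure D4:**
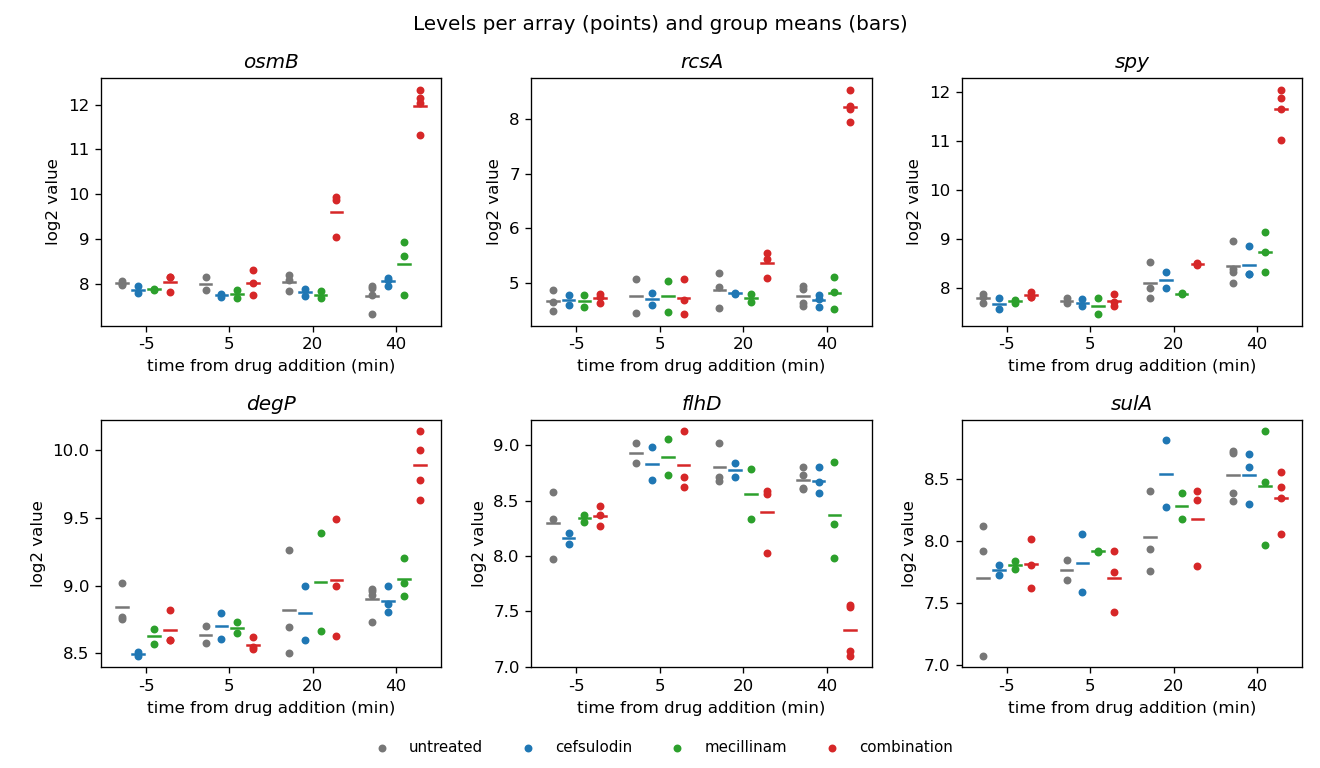
Log2 levels of osmB, rcsA, spy, degP, flhD and sulA (vertical axes) are shown against time from drug addition in min (horizontal axes), with a point per array, a short bar at each group mean and a colour per treatment. At 40 min osmB averages 11.96 with the combination and 7.73 in untreated cultures, and flhD 7.33 and 8.69.

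Cefsulodin alone at 40 min left the genes that rose with the combination near their untreated levels. osmB differed by 0.33 ± 0.22 (SE), rcsA by -0.07, spy by 0.04, cpxP by 0.34, degP by -0.01 and flhD by -0.01. wza differed by 0.07, rpoE by -0.23, sulA by 0.00, ibpB by 0.36, mrcA by 0.03, mrcB by 0.10 and mrdA by -0.12. The count was 0 genes (limma), with 135 at an unadjusted p below 0.05. All 20 TCA and glyoxylate genes were higher, with a median of 0.32 (camera, adjusted p = 0.0018), among them aceB (0.80), aceA (0.71), gltA (0.71) and sucA (0.65). All 7 curli genes were lower, with a median of -0.17 (adjusted p = 0.0018). In both lists 0 members passed over all genes or adjusted over the list alone, and adjusted p = 0.89 with an estimated correlation for each. Without untreated array 3 both calls ended (adjusted p = 0.291 for TCA and 0.0651 for curli), and the TCA call also ended without cefsulodin array 3 (0.0951). Without untreated array 2, 5 lists were called, heat shock (0.0116), flagella (0.0397) and ribosomal proteins (0.0397) being added. Heat shock also passed without cefsulodin array 1 (0.0008). The peptidoglycan synthesis list passed without untreated array 4 (0.008), with the replicate block (0.0414) and with the block within each time (0.0362). With the latter, heat shock (0.0023) and Cpx (0.0389) passed as well.

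At earlier times cefsulodin gave 0 changed genes (limma), with 52 at an unadjusted p below 0.05 at 5 min, 313 at 20 min and 98 at -5 min. osmB differed by -0.26 at 5 min and -0.22 at 20 min, and sulA by 0.51 at 20 min. At 20 min the count was 17 without cefsulodin array 1 and 4 without untreated array 1. At 5 min it was 4 without untreated array 1, 1 without cefsulodin array 1 and 3 without cefsulodin array 2, and at -5 min 5 and 2 without cefsulodin arrays 1 and 2. In these fits a lone array was assumed to vary like the other groups. The cefsulodin arrays at 20 min were numbered 1 and 2, while untreated cultures also had array 3. Genes at an unadjusted p below 0.05 there (limma) numbered 90 without untreated array 3, 448 without array 1 and 737 without array 2. The lists at 20 min were not tested again without these arrays. With all arrays, camera called 2 lists at -5 min, before the drug, phage shock (adjusted p = 0.0076) and colanic acid (0.0405), and 0 at 5 min. At 20 min it called 3 lists, ribosomal proteins (5.9e-11), TCA and glyoxylate (0.005) and sigma E (0.0088). With an estimated correlation 0 of these lists passed, and fry called 0.

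Mecillinam alone at 40 min showed its largest Rcs differences in ymgD (0.98), osmB (0.71 ± 0.22, SE), ymgG (0.54) and bdm (0.29), none past the test. The SDs over the 3 mecillinam arrays were 0.98, 0.62, 0.56 and 0.20 in that order. In untreated cultures they were 0.13, 0.29, 0.10 and 0.17. rcsA differed by 0.06, spy by 0.30, cpxP by 0.67, degP by 0.15 and flhD by -0.32. wza differed by -0.04, rpoE by 0.20, sulA by -0.09, ibpB by 0.43, mrcA by 0.08, mrcB by -0.02 and mrdA by -0.08. The count was 0 genes (limma), with 70 at an unadjusted p below 0.05, and 1 without mecillinam array 1. Of 18 other Rcs genes 16 were higher, 0 passed over all genes and 2 rose adjusted over the list alone. Their median was 0.09 (camera, adjusted p = 2.4e-05, and adjusted p = 0.397 with an estimated correlation). The flagellar genes had a median of -0.15 with 0 past either way (adjusted p = 0.00011, and adjusted p = 0.81 with an estimated correlation), led by flgN (-0.49) and flgE (-0.38).

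The mecillinam flagellar call ended without mecillinam array 2 (adjusted p = 0.429), where 1 list was called. Lists called numbered 6 without untreated array 4, mecillinam array 1 or mecillinam array 3, 5 without untreated array 2 and 4 without untreated array 1. With the replicate block 6 lists were called, adding Cpx (adjusted p = 0.0111), heat shock (0.049), oxidative stress (0.0145) and outer membrane proteins (0.0074). With an estimated correlation none of these 4 passed (adjusted p = 0.92, 0.92, 0.562 and 0.108). With the block within each time 7 were called, adding the ribosomal proteins (0.0167, and adjusted p = 0.867 with an estimated correlation), and the other 4 again did not pass with an estimated correlation (adjusted p = 0.21, 0.597, 0.302 and 0.0834). At -5 min, before the drug, camera called 1 list for mecillinam, phage shock (adjusted p = 0.0412). It called 0 at 5 min and 1 at 20 min, TCA and glyoxylate (4.2e-05). With an estimated correlation 0 of these passed, and fry called 0. The mecillinam arrays at 20 min were numbered 1 and 2, while untreated cultures also had array 3. Genes at an unadjusted p below 0.05 there (limma) numbered 99 without untreated array 3, 396 without array 1 and 810 without array 2. At these earlier times mecillinam gave 0 changed genes (limma), with 32 at an unadjusted p below 0.05 at 5 min, 353 at 20 min and 46 at -5 min. At 20 min the count was 14 without mecillinam array 1 and 8 without untreated array 2. At 5 min it was 4 without untreated array 1, 1 without mecillinam array 1 and 2 without mecillinam array 2, and at -5 min 3 without mecillinam array 2.

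Mecillinam at 0.03 µg/ml and cefsulodin at 10 µg/ml were compared at matched times, their concentrations being different. At 40 min osmB differed by 0.39 (95% interval -0.10 to 0.87), rcsA by 0.14 (-0.25 to 0.52), spy by 0.26 (-0.18 to 0.70) and flhD by -0.31 (-0.69 to 0.07), mecillinam minus cefsulodin. The counts were 0 genes at 40, 20 and 5 min (limma), with 66, 77 and 29 at an unadjusted p below 0.05. The 95% interval at 40 min had a median half-width of 0.303 log2 units. It lay within 1 log2 unit of 0 for 3990 of 4185 genes and reached beyond it for 195, so larger differences in those are not excluded. Without mecillinam array 1 the count at 40 min was 1. At 5 min it was 3 without cefsulodin array 2, and 1 and 2 without mecillinam arrays 1 and 2. With array weights 18 genes changed at 40 min, 4 up and 14 down.

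Camera called 6 lists between mecillinam and cefsulodin at 40 min, 0 of them with an estimated correlation and 0 by fry. The other Rcs genes were higher with mecillinam by a median of 0.11 (ymgD 0.93 and ymgG 0.57, adjusted p = 0.295 with an estimated correlation). TCA and glyoxylate genes differed by a median of -0.25 (adjusted p = 0.943 with an estimated correlation), outer membrane protein genes by -0.14, among them ompF at -0.49 (adjusted p = 0.353 with an estimated correlation), and peptidoglycan synthesis genes by -0.13 (adjusted p = 0.505 with an estimated correlation). The medians were -0.13 for the flagellar genes (adjusted p = 0.943 with an estimated correlation) and 0.08 for curli (adjusted p = 0.922 with an estimated correlation), whose call ended with the block within each time (adjusted p = 0.0523). In these lists 0 members passed over all genes. Adjusted over the list alone, 1 outer membrane protein gene fell.

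The combination was set directly against each drug at 40 min. Against cefsulodin, osmB rose by 3.91 ± 0.22 (SE, log2), and ymgD was 12.3-fold higher, spy 9.08-fold and ivy 7.29-fold, and flhD was 2.54-fold lower. Against mecillinam, osmB was 11.5-fold higher, spy 7.58-fold, ymgD 6.47-fold and ivy 6.14-fold, and flhD was 2.06-fold lower. rcsA rose in both, to 8.22 from 4.68 with cefsulodin and 4.82 with mecillinam. degP rose too, 1.79-fold against mecillinam (adjusted p = 0.0026) and also against cefsulodin (adjusted p = 0.0002). wza rose by 0.48 against mecillinam and differed by 0.37 (adjusted p = 0.1) against cefsulodin. Of 18 other Rcs genes 12 rose in both comparisons, over all genes and adjusted over the list alone (adjusted p = 1.4e-07 and 2.2e-07 with an estimated correlation).

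Against cefsulodin 90 genes changed, 74 up and 16 down, and against mecillinam 62, 60 up and 2 down. A block within each time gave 144 genes changed against cefsulodin (102 up, 42 down) and 109 against mecillinam (106 up, 3 down). Array weights gave 471 against cefsulodin, where most then fell (206 up, 265 down), and 170 against mecillinam (143 up, 27 down). When only the groups compared were fitted, 45 (43 up, 2 down) and 37 (all up) changed. The largest falls against cefsulodin after flhD were in the operon of the proton-pumping NADH dehydrogenase, at -1.15 for nuoK, -1.05 for nuoL, -1.03 for nuoG and -1.03 for nuoJ. Those 4 calls ended without combination array 4 (adjusted p = 0.14, 0.104, 0.271 and 0.0833), without cefsulodin array 1 (0.246, 0.135, 0.319 and 0.136) and without cefsulodin array 3 (0.0775, 0.0531, 0.133 and 0.0515), as they did without both arrays numbered 4 (0.0941, 0.0882, 0.147 and 0.0516). None passed when only the groups compared were fitted (0.275, 0.149, 0.317 and 0.163). nuoG also did not pass without combination array 3 (0.070) or after either renormalization (0.0509 and 0.0567). The count against cefsulodin was 50 without cefsulodin array 1 and 57 without cefsulodin array 3. Against mecillinam yjfJ (-0.32) also fell, a call that ended without mecillinam array 1 (0.0647), mecillinam array 3 (0.169) or combination array 1 (0.0767), and neither flhD (0.0955) nor yjfJ (0.369) passed when only the groups compared were fitted. Camera called 11 lists against cefsulodin and 14 against mecillinam, 4 and 3 with an estimated correlation, which became 6 and 6 with the replicate block and 7 and 7 with the block within each time.

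Of the 66 genes that rose against untreated cultures, 50 also rose against both drugs alone. Simulations with no effect in any group at 40 min shared 0 (20 simulations). Data without effects leave few calls to share, so these simulations decide nothing. Independent lists would share 0.0167. The comparisons have the combination arrays in common. With those arrays split into pairs, the risers shared ranged from 40 to 43 for untreated with cefsulodin and from 36 to 42 for untreated with mecillinam (3 splits, each pair serving either comparison).

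The effect of the combination at 40 min was then tested against the sum of the effects of the drugs alone. rcsA exceeded that sum by 3.47 ± 0.25 (SE), osmB by 3.19 ± 0.32, spy by 2.89 ± 0.29, ivy by 2.65 and ymgD by 2.64. In all 42 genes were non-additive, 39 above the sum and 3 below, and with array weights 121 were, 85 above and 36 below. Of the 66 risers, 38 were above it. Both tests use the same combination and untreated arrays and are not independent. With those arrays split into pairs so that the tests shared none of them, 24 to 36 genes passed both upwards (6 values from 3 splits). Simulations gave 0 but leave out all effects, and independent lists would share 0.615. Of 18 other Rcs genes 12 exceeded the sum under both adjustments (adjusted p = 2.6e-06 with an estimated correlation), and of 23 colanic acid genes 4 over all genes and 8 adjusted over the list alone (adjusted p = 0.0963 with an estimated correlation). Of 24 general stress genes, osmY (2.12), yjbJ (1.90), osmE (1.18) and osmC (1.03) did, and 10 adjusted over the list alone (adjusted p = 0.0963 with an estimated correlation). degP exceeded the sum by 0.85 (adjusted p = 0.1) and did not pass, though it did with the block within each time (0.0047), with array weights (0.0004), and when only the groups compared or the arrays of that time were fitted (0.035 in each). The colanic acid and general stress lists each had adjusted p = 0.0423 with an estimated correlation when the replicate block was fitted.

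Below the sum were flhD (-1.03), the anaerobic ribonucleotide reductase gene nrdD (-0.83) and aslB (-0.59). The flhD call ended without untreated array 4 (adjusted p = 0.061), cefsulodin array 1 (0.106), mecillinam array 1 (0.198), combination array 1 (0.0698) or combination array 4 (0.0698). The nrdD call ended without any of 8 arrays and the aslB call without any of 10 (adjusted p up to 0.199 and 0.274). With the replicate block none of these 3 passed (adjusted p = 0.154, 0.145 and 0.308), nor with the block within each time (0.098, 0.135 and 0.285), without both arrays numbered 4 (0.138, 0.218 and 0.278) or when only the groups compared were fitted (0.115, 0.310 and 0.310).

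Untreated cultures at 40 min were set against those at -5 min as the background change of growth. tnaC, the leader peptide gene of the tryptophanase operon, rose from 4.98 ± 0.36 (SD, n = 3), also below the 25th percentile of probe sets, to 13.74 ± 0.31 (SD, n = 4), and tnaA, the tryptophanase gene, rose by 5.40 on the log2 scale. The next largest rises were 5.29 for the trehalose uptake gene treB, 5.29 for the glycerol facilitator gene glpF and 5.19 for glpQ, which encodes a glycerophosphodiester phosphodiesterase. ndh, the gene of the other NADH dehydrogenase, fell by 2.70, tsgA by 2.35, ibpA by 2.19, the glucose uptake gene ptsG by 1.95 and the acetate kinase gene ackA by 1.89. In total 892 genes changed, 421 up and 471 down. With each array shifted to one median the split was 330 up and 655 down, and after quantile normalization again 339 and 552. Time also separates these groups by growth stage, which the comparison does not part from it.

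With time, 13 of 20 TCA and glyoxylate genes rose in untreated cultures and 14 did adjusted over the list alone, with a median of 1.67 (adjusted p = 0.317 with an estimated correlation). sdhC rose by 3.13, sdhD by 2.75, sdhA by 2.58 and mdh by 2.17. Of 17 heat shock genes 11 fell, and 12 adjusted over the list alone, with a median of -1.15 (adjusted p = 0.317 with an estimated correlation), among them dnaK (-1.81) and dnaJ (-1.79). Of 35 peptidoglycan synthesis genes 14 fell and 1 rose, with 17 and 1 adjusted over the list alone (median -0.23, adjusted p = 0.304 with an estimated correlation). mrdA fell by 0.65. Of 26 division and shape genes 10 fell and 2 rose, with 14 and 2 adjusted over the list alone (median -0.38, adjusted p = 0.277 with an estimated correlation), and sulA rose by 0.83. Of 12 reference genes 4 fell, and the same number adjusted over the list alone (median -0.27, adjusted p = 0.184 with an estimated correlation). spy rose by 0.65. Camera called 10 lists, 0 of them with an estimated correlation, and fry called 11.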

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

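The tests of growth stage and of other splits of the arrays were set out before the results they bear on, and the other 5 tests were chosen after the result was seen. Between 40 and 20 min the effect of the combination differed for 31 genes by a test of the difference itself, all 31 larger at 40 min. Between 40 and 5 min it differed for 33, 32 of them larger at 40 min. The effect at 40 min exceeded that at 20 min by 2.98 on the log2 scale for rcsA, 2.83 for spy, 2.66 for osmB, 2.36 for ymgD, 2.34 for hslJ, 2.11 for ymgG, 1.93 for ivy, 1.93 for bdm, 1.62 for ycfJ and 1.36 for ypeC.

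Probe sets that name no gene here also responded. Of 3005 tested apart from the genes, 24 changed with the combination at 40 min, 21 up and 3 down, and 2 rose at 20 min. All of these were intergenic probe sets. The largest rise was 5.55 ± 0.18 (SE) at 40 min, above that of osmB (4.23), and the next 3.06. At 20 min the rises were 2.36 ± 0.21 and 0.82.

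In 4 of 78 gene and group pairs 1 array lay far from the others, the gap to the nearest being a share of the group's range above Dixon's 95% critical value, where chance gives 3.9 of 78. tnaA was 9.79 on combination array 4 at 40 min and 12.79 to 13.07 on the other 3 (share 0.914). ibpA was 8.16 on untreated array 2 and 7.71 to 7.75 on the others (0.913). nuoG was 11.49 on untreated array 4 and 12.31 to 12.45 on the others (0.848). glpQ was 12.99 on combination array 3 and 12.50 to 12.58 on the others (0.839).

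The first pattern weighed was the rise of 66 genes with the combination at 40 min, led by osmB, rcsA and spy. Growth stage shared by the cultures was predicted to move these genes from 20 to 40 min with cefsulodin too, by at least 0.494. Their median change there was -0.0617 (quartiles -0.21 and 0.12), short of that. A stage shared with untreated cultures of the same time cancels in this comparison, so the test decides nothing about the rise. Cefsulodin cultures cannot show a change of growth particular to the combination, which was not tested. A difference between the cultures before the drugs is argued against by a median of 0.0307 at -5 min (quartiles -0.08 and 0.11). Of 35 splits of the 8 arrays, 2 gave as many genes, the real one with 69 and another with 125 that put both arrays numbered 4 together, so chance was not excluded at 0.05 in this test, while among the 8 splits that part all 4 pairs the highest other count was 0. The other Rcs genes had medians of 1.52 to 1.98 over the 4 same-numbered pairs, and joint action of both drugs, the biological difference the design names, stays open as a hypothesis.

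The second pattern was the separation of the 20 min arrays numbered 2 from those numbered 1. The difference between them correlated across genes between every pair of treatments, at 0.276 to 0.797 over 6 pairs (genes are not independent replicates). The pattern was chosen from this separation, so these values restate it. They cannot tell a shared day or handling from a shared state of the cultures. A later point along the overall change from -5 to 40 min is argued against, the highest of 4 correlations with that change being 0.204 and the lowest -0.33. A course that turns between those times is not covered. No other explanation was tested.

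The third pattern was the higher level of heat shock genes and lower level of flagellar genes with the combination at 40 min, of which 0 of 17 and 2 of 46 passed over all genes, 0 and 13 with the replicate block, and 11 and 20 with the block within each time. Slower progress along the untreated time course, with all genes in proportion, would lower the TCA and glyoxylate genes by 0.67. Their median difference was -0.0346 (quartiles -0.06 and 0.17), which argues against such a proportional delay. In untreated cultures ibpA averaged 10.02, 11.14 and 7.84 at -5, 20 and 40 min, not a proportional course. A delay after 20 min therefore stays open. A single pair of cultures is argued against because 4 of 4 same-numbered pairs had both a higher heat shock median and a lower flagellar median. A response to both drugs stays open as a hypothesis, and other splits of the arrays gave as many lists called (6 of 35, the real one included).

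Other splits of the arrays were counted for the remaining comparisons, each number including the real split. For the untreated time course the real split stood clear of the others (1 of 35 splits, 892 genes, highest other 482), and chance was excluded. For the combination against cefsulodin the real split gave the most genes by a narrow margin (1 of 35, 90 genes, highest other 86). The same held for the combination against mecillinam (1 of 35, 62 genes, highest other 61). Another split came this close in each, so these 2 counts cannot decide about chance. Among the 8 splits that part as many pairs the highest others were lower, at 22 against cefsulodin and 20 against mecillinam. For the non-additive genes 3 of 100 drawn splits gave as many as the real 42, with 195 the highest other. The 195 genes, several times the real count, point to a structure of the samples, so this count cannot decide about chance either. For the lists called with the combination at 40 min, 6 of 35 splits gave as many as the real 12, with 18 the highest, so chance was not excluded. Among the 8 splits that part all 4 pairs, 2 gave as many, the real one included, and 18 was again the highest. Nor was chance excluded for the lists with cefsulodin at 40 min (24 of 35 for 2 lists, highest 9) and mecillinam at 40 min (27 of 35 for 2 lists, highest 8, and 3 of the 8 splits that part as many pairs, highest 6). Both gave 0 genes, a count that every split reaches by construction (35 of 35 for each, highest 7 and 4), so their splits decide nothing about genes.

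With 10 splits, a share under 0.05 is out of reach for 3 comparisons. The combination at 20 min gave 5 genes in the real split, 4 of 10 splits gave as many, and the highest other was 832. That split set untreated array 2 and combination arrays 1 and 2 against the rest, so that both arrays numbered 2 stood together. A count so far above the real one points to a structure of the samples by number, and the fit with a block within each time gave 9 genes. Among the 4 splits that part as many pairs the highest other was 0. Its lists numbered 1, with 9 of 10 splits giving as many and 10 the highest. At -5 min the combination gave 0 genes in all 10 splits, and mecillinam against cefsulodin at 40 min gave 0 with a highest other of 2 (10 of 10), counts that every split reaches by construction.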

How the results depend on the processing

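The block within each time, the fit of the arrays of the time points compared, the single listed symbol and the fits without the arrays numbered 2 or 4 were chosen after the data were seen. Over all settings, 383 summary values kept their side of the 1.5-fold range and 70 moved. Of the named genes, 2214 values kept their call or their lack of one, 16 gained a call and 101 lost it. With a call in either fit, 0 reversed direction. The direction of genes uncalled in both fits was not compared. The cause was not tested for any of the moved values, except that a 2-fold minimum and fits of fewer arrays or genes test less by construction. The 69 genes of the combination at 40 min all stayed called with each array shifted to one median, the mean of probe sets, array weights and both blocks, and 65 did after quantile normalization again. Without the dimmest 25% of genes, 51 of them were called. Signal over background was not measured.

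The replicate numbers paired the samples for the combination at 40 and 20 min, mecillinam at 40 min and the treated groups with each other at 40 min. Same-numbered arrays also correlated for cefsulodin (0.450 to 0.804) and mecillinam (0.561 to 0.737) at 20 min and mecillinam at 5 min (0.407). With 2 arrays per drug these are too few to tell a pairing. The block within each time gave 0 genes for each of them, and their lists were not tested with a block. With the replicate block the combination at 40 min changed 110 genes, and mecillinam at 40 min changed 6 lists. With the replicate block within each time, the combination at 40 min changed 205 genes, at 20 min 9 genes and 2 lists, and mecillinam at 40 min 7 lists, with 144 genes for the combination against cefsulodin and 109 against mecillinam. Not every pair with untreated cultures correlated above 0.1 for cefsulodin at 40 min (-0.01 to 0.47) and the combination at -5 min (0.03 to 0.32). For cefsulodin, numbers 1 and 2 gave 0.344 and 0.474 and number 3 gave -0.01. Its arrays correlated with same-numbered combination and mecillinam arrays at 40 min (0.283 to 0.527 and 0.375 to 0.725), so the numbers may carry a shared origin there too. The block within each time gave 5 lists for cefsulodin at 40 min and 1 gene for cefsulodin at -5 min, where 2 numbers are too few to tell. For the untreated time course the block within each time coincides with the groups and was not fitted. For the paired comparisons, the calls of the genes named for them that a block changed stand beside the results.

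With array weights the genes numbered 135 for the combination at 40 min (114 up, 21 down), 471 against cefsulodin (206 up, 265 down), 170 against mecillinam (143 up, 27 down), 18 for mecillinam against cefsulodin and 121 for non-additive genes. With only the groups compared they numbered 45 against cefsulodin, 37 against mecillinam and 0 for the combination at 20 min, and 0 again with the arrays of that time alone. Relative to the -5 min groups, 36 genes changed at 40 min and 1 at 20 min. Without the dimmest 25% 3 changed at 20 min. At a 2-fold minimum the counts were 32 at 40 min, 2 at 20 min, 44 against cefsulodin, 29 against mecillinam and 222 for the untreated time course. With an estimated correlation camera called 5 lists for the combination at 40 min and 0 for cefsulodin or mecillinam, for both of which fry called 0. Without the dimmest 25% 0 lists were called for cefsulodin, the TCA list having adjusted p = 0.0672 (camera) and the curli list no value there.

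Leaving out each array in turn, the genes ranged from 50 to 115 for the combination against cefsulodin, 3 to 6 for the combination at 20 min, 0 to 2 for it at 5 min, 0 to 17 for cefsulodin at 20 min, 0 to 4 at 5 min and 0 to 5 at -5 min. For mecillinam they ranged from 0 to 14 at 20 min, 0 to 4 at 5 min, 0 to 3 at -5 min and 0 to 1 at 40 min. For mecillinam against cefsulodin they ranged from 0 to 1 at 40 min and 0 to 3 at 5 min. The lists ranged from 2 to 9 for the combination at 20 min, 0 to 5 for cefsulodin at 40 min and 1 to 6 for mecillinam at 40 min.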

Other observations

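The genes in these paragraphs were chosen after their values were seen. Of the 69 genes that changed with the combination at 40 min, 35 belonged to no list. Those that rose included ypeC (2.50), the lipoprotein gene hslJ (2.45), ygaC (2.04), ygdR (1.88) and yegS (1.74), each of which also rose against both drugs alone. Of genes for enterobactin, the siderophore that takes up iron, entB (0.75), entE (0.54) and entH (0.50) rose against untreated cultures. eco (1.01), which encodes a periplasmic protease inhibitor, and lolA (0.70), a carrier of lipoproteins to the outer membrane, rose as well. The theme of these genes was not tested for enrichment.

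The 20 min arrays numbered 2 and 1 differed in the same genes over the treatments. Averaged over the 4 treatments, number 2 was higher by 3.02 for the glyoxylate gene aceA, 2.90 for the phosphate uptake gene pstS, 2.42 for aceB, 2.14 for ibpA and 2.07 for clpB. It was lower, at -3.10, for the nucleoside transport gene nupG, -2.52 for rpmC and -2.34 for rpsQ, ribosomal protein genes, and -2.10 for fis. By list, the medians were 0.89 for heat shock (0.81 to 1.16 over the treatments), 0.49 for Cpx (0.30 to 0.57), -1.03 for ribosomal proteins (-1.51 to -0.41) and -0.10 for the other Rcs genes (-0.26 to 0.02). With 1 array of each number per treatment, these are values without a test.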
